A study of Homo sapiens with 18 samples.

How the data were processed

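Expression was measured on 18 Affymetrix Human Gene 2.0 ST arrays of U937 cells, 3 in each of 6 groups named by the labels. The values used are the deposited log2 signals, which the authors made with RMA (background correction, quantile normalization and summary by probe set) per the submitters' processing notes; the version of that software was not given in the sources used here. Per the labels, RNA was extracted with TRIZOL and an RNeasy MinElute column and labelled with biotin. The raw arrays were not used here. The deposited table held 48226 probe sets. No label gives a scan date or a batch, and the replicate numbers of different groups were not taken as pairs. The numbers 50, 8 and 1 in the labels have no unit there.

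Probe sets were named with the array's annotation table, and symbols were updated by gene identifier to those of the RefSeq gene table. Of the probe sets, 16098 had 1 symbol, 0 had several and 32128 had none. The unnamed ones were not tested as genes, and how many of them changed is counted in the closing section. Where a gene had more than 1 probe set (779 genes), the one with the highest mean level over all arrays stood for it. This left 14884 genes, 11916 of them protein coding. No gene was removed for a low level. Because array signals are compressed near the background, changes of weakly expressed genes can be understated. The median of all values was 3.84 on the log2 scale.

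Genes were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean for each of the 6 groups was fitted to the log2 values, so that all groups shared 1 spread per gene with 12 residual degrees of freedom, which empirical Bayes then moderated. There were 13 comparisons: each of the 5 treatments against control, each combination against each of its agents, the inhibitors against each other, the combinations against each other, and the interaction of decitabine with each inhibitor. An interaction is the change with both agents minus the sum of the changes with each alone, on the log2 scale. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison are said to be called, higher or lower. A second count took those that also changed by at least 2-fold. The comparisons, the test, the gene lists and the alternatives below were chosen before the data were examined.

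A fixed set of 30 gene lists was written from general knowledge: DNA methylation enzymes, histone deacetylases and acetyltransferases, cancer-testis antigens, germline genes under promoter methylation, imprinted genes, type I interferon response, MHC class I presentation, MHC class II presentation, monocyte and macrophage markers, granulocyte genes, stem and progenitor genes, erythroid genes, megakaryocyte and platelet genes, B cell markers, T and NK cell markers, neuronal genes, epithelial and stromal markers, MYC and ribosome biogenesis, ribosomal proteins, DNA replication, G2 and mitosis, cell cycle inhibitors and p53 targets, BCL2 family and death receptors, NF-kB and inflammatory cytokines, unfolded protein and integrated stress response, heat shock chaperones, metallothioneins, cholesterol synthesis, lysosome, and polyadenylated histone genes. The 28 lists with at least 5 measured members were tested with camera from limma at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with the correlation estimated for each list, and the rotation test fry, were alternatives. Calls of list members are given over all genes and, as a second count, with the adjustment over the list alone.

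Genes are named in the text by a rule set in advance. It takes the 10 largest rises and 10 largest falls of each comparison among called protein-coding genes whose arrays were fully separated (a condition that does not apply to interactions), up to 4 called members of each list, and 14 genes of drug targets and myeloid differentiation. CDKN1A and ITGAM, which belong to the last set, were on no named probe set, and 1 further gene of that set is not reported here. Copies of near-identical genes, such as those of the CTAG1, GAGE, MT1 and HSPA1 families, are not told apart by the probes.

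For pairs of comparisons, changes were correlated across genes and shared calls were counted. Because comparisons with the same controls correlate without any effect, 100 simulations drew arrays with each gene's residual spread and no effect, and the same values were computed, the shared calls in 1 further simulation. Principal components were computed on gene levels centred per gene.

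Before use the code was tested on effects planted in 14884 simulated genes with the measured residual spread. In decitabine against control 35.8% of changes of 1.5-fold, 79.1% of 2-fold and 98.5% of 4-fold were recovered, with 12 false among 154 calls. In decitabine plus panobinostat against control the shares were 40.3%, 85.1% and 100%, with 7 false among 157 calls. For the interaction of these agents they were 14.9%, 46.3% and 97.0%, with 8 false among 113 calls, so an interaction below 2-fold was more often missed than found. Of lists shifted by 0.5 (log2) 20 of 20 were called, and of unchanged ones 0 of 540, but correlated genes were not tested.

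Alternatives tried were the replicate number as a block, the mean over a gene's probe sets, every probe set tested on its own, a filter on dim values that left 10837 genes, quantile normalization applied again, centring each array on its median, a fit with only the groups of the comparison, empirical Bayes with trend and robust settings, array weights, a test against a 1.2-fold change (treat), and leaving out each array in turn. Figures and the tests of the closing section used R 4.3.3 and, for the figures, Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. With groups of 3 no array was judged an outlier and none was left out.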

Results

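Gene expression was measured in U937, an established human cell line of monocytic lineage grown from a histiocytic lymphoma, on Affymetrix Human Gene 2.0 ST arrays. There were 18 arrays in 6 groups of 3: untreated control, decitabine, panobinostat, valproic acid, decitabine plus panobinostat, and decitabine plus valproic acid. Decitabine is a cytosine analogue that traps DNA methyltransferases and lowers DNA methylation in dividing cells. Panobinostat and valproic acid inhibit histone deacetylases. Per the labels, decitabine was given in 3 pulses of 24 h, and the histone deacetylase inhibitor was added for 24 h with the last pulse. The labels carry the numbers 50, 8 and 1 for decitabine, panobinostat and valproic acid without a unit, so the doses of the inhibitors are not taken as matched. The deposited log2 values of the 18 arrays ran from 2.29 to 14.57, with array medians between 3.81 and 3.87. Arrays have no read depth, and their number limits the precision. All groups have n = 3, and each error given with a change is the standard error (SE) from limma.

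Arrays of the same group correlated across genes at 0.986 to 0.991, and arrays of different groups at 0.963 to 0.990. The first principal component held 34.2% of the variance and ran from the controls to the 3 arrays of decitabine plus panobinostat. The second, with 16.7%, separated the decitabine arrays from those of both inhibitors given alone. Among the arrays of decitabine plus valproic acid, replicate 1 lay at 12.04 on the first component, against 23.9 and 30.6 for the other two. No label names a culture date or a batch, so the adjusted p-values below measure the spread between arrays, part of which may be technical, and nothing says whether the 3 arrays of a group came from separate cultures.

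**Figure D1:**
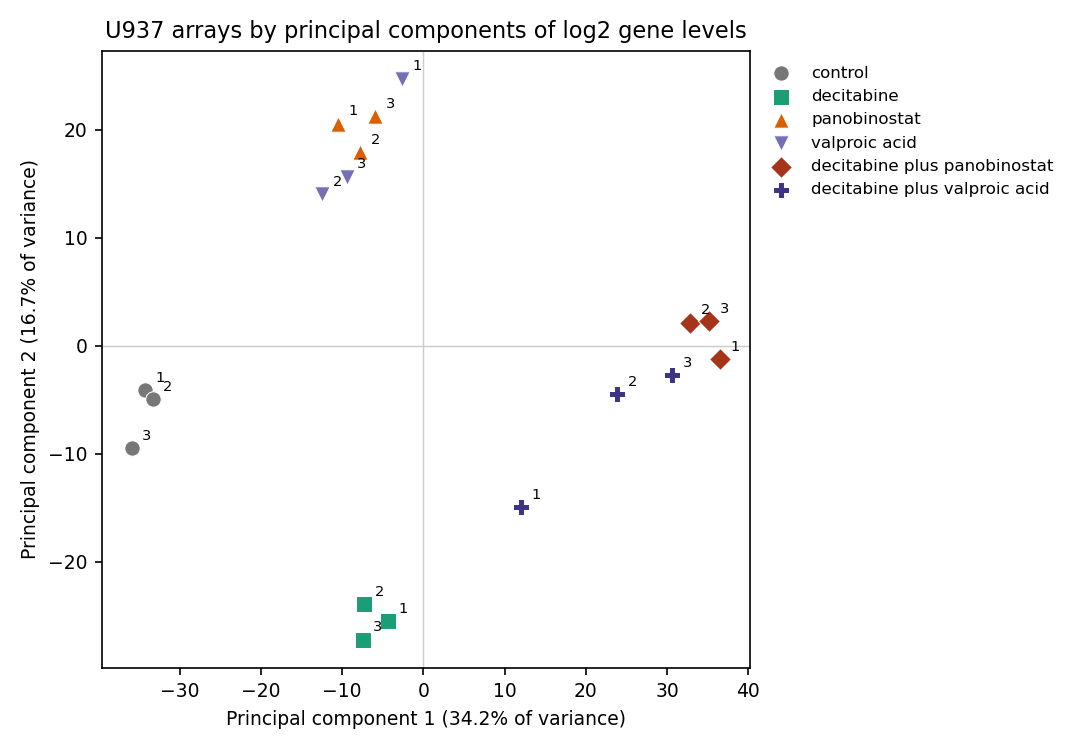
Each point is 1 array, placed by the first (34.2% of variance) and second (16.7%) principal component of the log2 levels of 14884 genes, with color and shape for the group and the replicate number beside it. The combination arrays lie opposite the controls on the first component, and the decitabine arrays lie opposite the panobinostat and valproic acid arrays on the second.

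Of 14884 genes tested, 590 passed an adjusted p of 0.05 with decitabine, 1100 with panobinostat, 1112 with valproic acid, 3447 with decitabine plus panobinostat and 2524 with decitabine plus valproic acid, each against control. With at least a 2-fold change the counts were 212, 312, 289, 1144 and 714. In comparisons of 2 groups, named genes with a call had their 3 treated arrays all above or all below the 3 arrays they were compared with, unless said otherwise, which chance alone gives for 10% of genes.

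**Figure D2:**
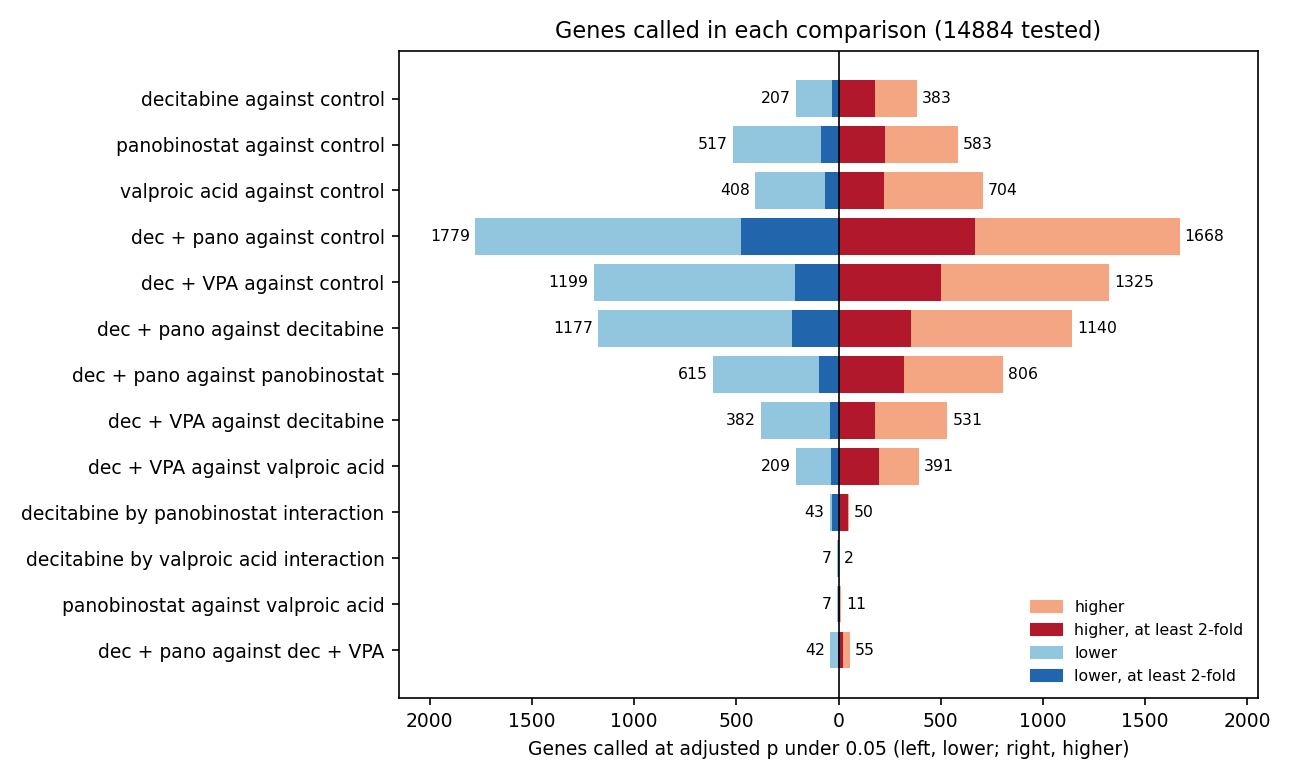
Bars give the number of genes called higher (right) or lower (left) at an adjusted p under 0.05 in each of 13 comparisons, with the part of at least 2-fold in the darker color. The combinations against control had the longest bars, and the decitabine by valproic acid interaction (9 genes) and panobinostat against valproic acid (18 genes) the shortest.

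The comparison of decitabine with control asks what the methyltransferase inhibitor did alone. Germline genes, a blood stem cell marker and a group of myeloid and interferon genes rose. CD34, a surface glycoprotein of hematopoietic stem and progenitor cells (probe set 16698801), rose most, by 4.73 on the log2 scale (SE 0.28), or 26.5-fold, from a control level of 4.32 (SD 0.17). TKTL1, a transketolase-like gene expressed in testis, rose by 3.78 (SE 0.34), and CCL1, a chemokine, by 3.74 (SE 0.20). The meiotic chromosome protein HORMAD1 rose by 3.48, MAEL, which acts in silencing transposons in germ cells, by 3.54, and the germ cell nuclear protein GCNA by 3.42. Of 590 genes called, 383 were higher and 207 lower, but 178 of the 212 changes of at least 2-fold were rises. The falls were smaller: RYR2, a calcium release channel, changed by -1.71 (SE 0.21), the melanin synthesis enzyme TYRP1 by -1.65 (SE 0.16) and ASNS, asparagine synthetase, by -1.06 (SE 0.19).

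Among gene lists fixed before the data were examined, 11 were called with decitabine, 10 higher and 1 lower. Of 10 measured cancer-testis antigens 4 were higher and 6 not called (5 higher when adjusted over the list alone), among them PRAME at 2.61 (SE 0.23) and CTAG1A at 1.35 (SE 0.26), a gene whose near-identical copy CTAG1B cannot be told from it by these probes. Of 18 germline genes under promoter methylation 6 were higher (7 over the list alone), including DAZL, an RNA-binding protein of germ cells, at 2.25 (SE 0.22). Of 29 type I interferon response genes 9 were higher (11 over the list alone), such as IFIT5 at 2.36 (SE 0.35) and the antiviral membrane protein IFITM3 at 1.37 (SE 0.19). Of 25 monocyte and macrophage markers 6 were higher (7 higher and 2 lower over the list alone): TYROBP, a signaling adaptor of myeloid receptors, reached 2.91 (SE 0.17), the receptor CSF1R 2.41 (SE 0.30), the costimulatory ligand CD86 2.11 (SE 0.18) and lysozyme, LYZ, 1.67 (SE 0.19). Of 19 stem and progenitor genes 3 were higher (1 more lower over the list alone), with the transcription factor GATA2 at 2.61 (SE 0.24). Of 17 T and NK cell markers 5 were higher, among them perforin, PRF1, at 2.63 (SE 0.26), and the T cell signaling proteins LAT at 1.41 and LCK at 1.27. In the camera test the adjusted p of these lists, in the order given, was 1.42e-05, 1.49e-05, 1.49e-05, 0.000189, 0.000579 and 6.17e-05. With an estimated correlation it was 0.00668, 0.0311, 0.0275, 0.00668, 0.0185 and 0.00668, the highest value over the 8 alternatives for each list, and the lowest values were 2.11e-06, 6.71e-07, 9.44e-06, 5.33e-06, 1.76e-05 and 1.76e-05.

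5 more lists were called with the preset correlation but not with an estimated one. Of 11 metallothioneins, which bind metal ions, 2 were higher (3 over the list alone), with MT1H at 2.26 (SE 0.17). Of 17 lysosome genes 3 were higher (6 over the list alone). None of 26 genes of G2 and mitosis was called, and their median was 0.14. The adjusted p of these 3 lists rose from 0.000579, 0.000667 and 0.00306 to 0.0506 for each with an estimated correlation, and their lowest values over the alternatives were 0.000347, 0.000413 and 0.000698. Of 19 genes of MYC and ribosome biogenesis 2 were lower (4 over the list alone), with an adjusted p of 0.000187 and of 0.218 with an estimated correlation (lowest alternative 7.5e-05). Of 22 genes of NF-kB and inflammatory cytokines 2 were higher and 1 lower (3 and 1 over the list alone), with an adjusted p of 0.0153, of 0.143 with an estimated correlation (lowest alternative 0.00325) and of 0.0853 without control replicate 3. Leaving out 1 array took the count of 590 genes to 366 without control replicate 1, 361 without control replicate 2 and 366 without decitabine replicate 1, and 253 genes were called whichever of the 6 arrays was left out.

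The comparison of panobinostat with control asks what this hydroxamate inhibitor did alone. LGR5, a receptor for R-spondins known from intestinal stem cells (probe set 16754134), rose by 3.80 (SE 0.24) from a control level of 4.10 (SD 0.58). The sialic acid-binding B cell lectin CD22 rose by 3.40 (SE 0.27) and the metalloprotease ADAM28 by 3.11 (SE 0.21). STAR, which carries cholesterol into mitochondria, fell by 1.78 (SE 0.29) and the transcription factor NFIX by 1.69 (SE 0.23). Of 1100 genes called 583 were higher and 517 lower, with 225 and 87 at 2-fold or more. The count was 659 without control replicate 3, and 504 genes were called whichever array was left out.

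Genes of MYC and ribosome biogenesis fell as a group with panobinostat: 8 of 19 were lower and none higher (15 lower over the list alone), with a median of -0.57 and an adjusted p of 8.74e-10 in the camera test. With an estimated correlation the adjusted p was 0.138, the highest of the alternatives, which began at 3.96e-10. ODC1, the first enzyme of polyamine synthesis and a member of this list, fell by 0.58 (SE 0.10). Monocyte and macrophage markers rose, 8 of 25 higher and none lower, with CSF1R at 1.94 (SE 0.30), LYZ at 1.71 (SE 0.19) and the calgranulin S100A9 at 1.40 (SE 0.23). This list had an adjusted p of 6.03e-05 and of 0.0071 with an estimated correlation, the highest alternative (lowest 7.86e-06). Of 29 interferon response genes 6 were higher and 1 lower, including SAMD9L at 1.36 (SE 0.18) and IFI44 at 1.11 (SE 0.17), with an adjusted p of 0.00404 and of 0.139 with an estimated correlation (lowest alternative 0.00313). Lower members were 3 of 23 in DNA replication (5 over the list alone), 3 of 19 ribosomal proteins (4) and 2 of 17 in cholesterol synthesis (4), with adjusted p of 0.00138, 0.00674 and 0.00746. Under an estimated correlation these became 0.166, 0.166 and 0.138, and their lowest alternatives were 0.0011, 0.00365 and 0.000908.

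The other 5 lists called with panobinostat were lost without single arrays. Of 17 lysosome genes 3 were higher, with the growth factor precursor GRN at 1.15 (SE 0.22); the adjusted p was 0.0265, 0.166 with an estimated correlation, 0.0621 without control replicate 2 and 0.0656 without panobinostat replicate 2. Stem and progenitor genes (3 higher and 1 lower of 19, or 4 and 1 over the list alone; adjusted p 0.0408) were not called with an estimated correlation (0.139), without control replicate 2 (0.0532), control replicate 3 (0.0602) or panobinostat replicate 2 (0.116). NF-kB and inflammatory cytokine genes had 4 of 22 higher (5 over the list alone) at an adjusted p of 0.0408, with the cyclooxygenase PTGS2 at 1.95 (SE 0.28). They were lost with an estimated correlation (0.166), without control replicate 2 (0.0532), control replicate 3 (0.096) or panobinostat replicate 1 (0.0713). Heat shock chaperones, 3 of 12 lower (4 lower and 1 higher over the list alone), included the mitochondrial chaperonin HSPD1 at -1.13 (SE 0.18). Their adjusted p of 0.0408 became 0.139 with an estimated correlation, and 0.0585, 0.0873, 0.0541 and 0.0656 without control replicate 2, control replicate 3, panobinostat replicate 1 and panobinostat replicate 2. Genes of the unfolded protein and integrated stress response, 1 higher and 3 lower of 14 (2 and 6 over the list alone), included the serine synthesis enzyme PSAT1 at -1.14 (SE 0.11). Their adjusted p of 0.0408 became 0.166 with an estimated correlation, 0.0672 without control replicate 1, 0.0602 without control replicate 3 and 0.14 without panobinostat replicate 3. In order, the lowest alternatives of these 5 lists were 0.0108, 0.00512, 0.0109, 0.00116 and 0.00363.

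The comparison of valproic acid with control asks the same of the second inhibitor. LGR5 rose by 3.61 (SE 0.24), CD22 by 3.16 (SE 0.27), CAPN6, a calpain-like protein, by 2.97 (SE 0.29), ADAM28 by 2.95 (SE 0.21) and SLFN5, an interferon-responsive gene, by 2.45 (SE 0.31). JADE2, a PHD finger protein, fell by 1.74 (SE 0.20), STAR by 1.73 (SE 0.29), MTHFD1L, a mitochondrial enzyme of folate metabolism, by 1.39 (SE 0.20), and the acetyltransferase gene KAT2A by 1.15 (SE 0.15). The transcription factor MYC itself fell by 1.03 (SE 0.22). Of 1112 genes called 704 were higher and 408 lower, with 220 and 69 at 2-fold or more. The count was 729, 653 and 508 without control replicate 1, control replicate 3 and valproic acid replicate 1, and 420 genes were called whichever array was left out.

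Of 19 genes of MYC and ribosome biogenesis 9 were lower with valproic acid and none higher (15 lower over the list alone), with the ribosome assembly factors NIP7 at -0.87 (SE 0.14) and WDR43 at -0.86 (SE 0.11). The list had an adjusted p of 3.51e-12 and of 0.0748 with an estimated correlation (lowest alternative 4.28e-12). Of 17 lysosome genes 7 were higher (adjusted p 8.35e-05, and 0.0661 with an estimated correlation), with GRN at 1.30 (SE 0.22), the calcium channel MCOLN1 at 0.84 (SE 0.18) and the sphingolipid activator precursor PSAP at 0.75 (SE 0.15). Of 25 monocyte and macrophage markers 5 were higher and 1 lower (9 and 1 over the list alone), among them CSF1R at 1.46 (SE 0.30) and the receptor TREM1 at 1.17 (SE 0.18). This list had an adjusted p of 0.0044, and of 0.0661 with an estimated correlation (lowest alternatives 2.64e-05 for lysosome and 0.000295 for monocyte genes). DNA replication genes, 2 of 23 lower (8 lower and 1 higher over the list alone), and ribosomal proteins, 1 of 19 lower (4 over the list alone), had an adjusted p of 0.000275 and 0.000529, which became 0.211 and 0.145 with an estimated correlation (lowest alternatives 0.000172 and 0.000311). 3 further lists were lost without single arrays. Interferon response genes, 7 of 29 higher (8 higher and 1 lower over the list alone; adjusted p 0.0449), were lost with an estimated correlation (0.24), without control replicate 3 (0.158) or valproic acid replicate 1 (0.099). Granulocyte genes, 2 of 18 lower (3 over the list alone), had an adjusted p of 0.048 and were lost with an estimated correlation (0.145), without control replicate 1 (0.169), control replicate 3 (0.0539) or valproic acid replicate 2 (0.168). Genes of G2 and mitosis, 2 of 26 higher, had an adjusted p of 0.0335 and were lost with an estimated correlation (0.188), without control replicate 1 (0.0582), control replicate 2 (0.0602) or valproic acid replicate 3 (0.107). The lowest alternatives of these 3 lists were 0.0101, 0.00384 and 0.00322.

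The inhibitors changed many genes in the same direction. Of the genes called with panobinostat and with valproic acid, 393 were higher in both and 247 lower in both, against 27.6 and 14.2 for independent calls, and none was called in opposite directions. The 0 shared calls of 1 no-effect simulation are no baseline, as it has nothing to call. The changes correlated at r = 0.793 (Spearman 0.682), though genes are not independent replicates. Shared controls alone gave r = 0.499 in 100 no-effect simulations. The covariance was 0.102 against 0.0192 in those simulations. The same calculation for decitabine gave r = 0.395 with panobinostat and 0.389 with valproic acid (Spearman 0.382 and 0.427), below the 0.4999 and 0.4996 that shared controls alone gave, while the covariance of 0.04996 and 0.04805 was above the simulated 0.0192. There were 132 and 130 shared rises, 57 and 53 shared falls, and 12 and 9 genes called oppositely. For the combinations r was 0.899 (Spearman 0.804, simulated 0.501) and the covariance 0.257 (simulated 0.0192). They shared 1086 rises and 979 falls, and 1 gene was called oppositely. Both hold decitabine, so these do not show how alike the inhibitors are. Only these 4 pairs were computed. The 3 controls were not divided, which would leave 1 side a single array, so shared arrays may give part of these values.

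Compared with each other at doses that are not matched, panobinostat and valproic acid differed in 18 genes, 11 higher and 7 lower with panobinostat. CCL1 was higher by 1.49 (SE 0.20), the tetraspanin TSPAN8 by 0.99 (SE 0.14) and the desmosomal cadherin DSC3 by 0.88 (SE 0.12), and ULBP1, a ligand of the NK cell receptor NKG2D, was lower, at -1.04 (SE 0.14). Each had an adjusted p of 0.0074 and kept its call with any 1 array left out. In a fit of these 6 arrays alone no gene was called. CCL1, TSPAN8 and ULBP1 then had an adjusted p of 0.136 and DSC3 of 0.176, and their lowest value over the alternatives was 0.00488. The count was 9 without panobinostat replicate 1, 9 without panobinostat replicate 3 and 4 without valproic acid replicate 3. At an unadjusted p under 0.05 there were 1349 genes. The camera test called 7 lists, none with a called member: only genes of G2 and mitosis, lower with panobinostat (median -0.17, adjusted p 0.00025), kept the call with each array left out, and their adjusted p was 0.071 with an estimated correlation (lowest alternative 4.66e-05). The other 6 lists, at adjusted p of 0.026 to 0.0336, were lost with an estimated correlation (0.113 to 0.269).

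Decitabine plus panobinostat against control shows the whole effect of the first combination. TKTL1 (probe set 17108264) rose by 6.02 (SE 0.34) from 3.32 (SD 0.17) in control and PRF1, the pore-forming protein of cytotoxic lymphocytes, by 4.91 (SE 0.26) from 3.60. Both control levels lay under the median of all values (3.84), so the sizes of these rises are uncertain. CD34 rose by 5.48 (SE 0.28), or 44.6-fold. The lysophospholipid receptor GPR34 rose by 4.64 (SE 0.25) and the short-chain dehydrogenase DHRS2 by 4.37 (SE 0.43). JADE2 fell by 3.01 (SE 0.20), MTHFD1L by 2.69 (SE 0.20) and the nuclear import receptor IPO4 by 2.09 (SE 0.26). Of 3447 genes called, 23.2% of those tested, 1668 were higher and 1779 lower, with 666 and 478 at 2-fold or more; 2199 were called whichever array was left out.

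Genes of the interferon response rose and genes of growth and DNA replication fell with this combination. Of 29 interferon genes 22 were higher and 7 not called, with a median of 0.97. IFI44L rose by 3.00 (SE 0.26), IFIT5 by 2.83 (SE 0.35), IRF9, a subunit of the transcription factor that interferon activates, by 2.80 (SE 0.30), and the RNA sensor RIGI by 2.22 (SE 0.15). Of 19 genes of MYC and ribosome biogenesis 18 were lower, with a median of -1.10: NOP16 fell by 1.95 (SE 0.33), RRS1 by 1.79 (SE 0.23), MYC by 1.63 (SE 0.22) and nucleolin, NCL, by 1.59 (SE 0.29). Of 23 DNA replication genes 18 were lower, with a median of -0.58, among them GINS3 at -1.59 (SE 0.20), CDC45 at -1.12 (SE 0.14), thymidylate synthase, TYMS, at -1.06 (SE 0.16) and the helicase subunit MCM7 at -0.82 (SE 0.15). The camera test gave an adjusted p of 1.78e-14, 1.78e-14 and 7.53e-09. An estimated correlation, the highest of the alternatives, gave 0.00256, 0.0235 and 0.0298, and the lowest alternatives were 5.68e-15, 1.66e-14 and 6.6e-09.

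Monocyte, stem cell, lymphoid, germline, lysosome and metallothionein lists also rose, while the lists of other cell types were not called. Of 25 monocyte and macrophage markers 11 were higher and none lower (11 and 1 over the list alone), with TREM1 at 3.23 (SE 0.18) and LYZ at 2.24 (SE 0.19). Of 19 stem and progenitor genes 10 were higher, with GATA2 at 2.72 (SE 0.24) and the ETS factor ERG at 1.23 (SE 0.24). Of 17 T and NK cell markers 8 were higher, with LAT at 2.73 (SE 0.21), LCK at 2.10 (SE 0.19) and the adhesion receptor CD2 at 1.88 (SE 0.22). Of 18 germline genes 9 were higher, with MAEL at 3.96 (SE 0.25) and DAZL at 3.20 (SE 0.22), and of 10 cancer-testis antigens 5 (6 over the list alone), with PRAME at 3.21 (SE 0.23). Of 17 lysosome genes 9 were higher, with GRN at 1.66 (SE 0.22) and PSAP at 1.39 (SE 0.15), and of 11 metallothioneins 5 (6 over the list alone), with MT1H at 3.18 (SE 0.17). Lower were 8 of 17 cholesterol synthesis genes (9 over the list alone), with mevalonate kinase, MVK, at -1.01 (SE 0.18). The adjusted p of these 8 lists was 3.54e-05, 0.000166, 0.000151, 2.92e-05, 0.000166, 5.73e-05, 0.000457 and 0.00409. Under an estimated correlation, the highest of the alternatives, it ran from 0.00412 for the monocyte list to 0.0352 for metallothioneins, and the lowest alternatives ran from 9.96e-09 to 6.86e-06. Ribosomal proteins, 9 of 19 lower (11 over the list alone), had an adjusted p of 0.000533 and of 0.0809 with an estimated correlation (lowest alternative 8.4e-05).

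The other lists were not called with this combination, though single members were. NF-kB and inflammatory cytokines had 6 of 22 higher and 1 lower (adjusted p 0.0511), with PTGS2 at 3.73 (SE 0.28) and TRAF1, an adaptor of TNF receptors, at 3.44 (SE 0.21). The BCL2 family and death receptors had 5 of 19 higher and 1 lower (6 and 2 over the list alone; 0.0633), with the pro-apoptotic BIK at 2.52 (SE 0.39) and BMF at 1.60 (SE 0.28). Of 14 cell cycle inhibitors and p53 targets 3 were higher (2 over the list alone; 0.374), with TP53INP1 at 2.97 (SE 0.39). B cell markers had 3 of 14 higher and 1 lower (4 and 2 over the list alone; 0.132), with CD22 at 3.20 (SE 0.27) and CD24 at 2.49 (SE 0.14). Heat shock chaperones went both ways, 4 higher and 4 lower of 12 (4 and 5 over the list alone; 0.538): HSPA1A, which the probes cannot tell from its near-identical copy HSPA1B with certainty, was at 1.45 (SE 0.29) and HSPD1 at -1.55 (SE 0.18). Histone deacetylases and acetyltransferases had 6 higher and 4 lower of 28 (6 and 6 over the list alone; 0.899), with KAT2A at -1.50 (SE 0.15) and HDAC5 at 1.36 (SE 0.17). Imprinted genes had 2 higher and 1 lower of 16 (0.479), with PEG10 at 2.96 (SE 0.18). Granulocyte genes had 2 higher and 4 lower of 18 (2 and 5 over the list alone; 0.196), with the G-CSF receptor CSF3R at -1.86 (SE 0.22). The unfolded protein and integrated stress response had 2 higher and 4 lower of 14 (0.254), with PSAT1 at -1.48 (SE 0.11).

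Fewer members passed in the remaining lists. Neuronal genes had 4 higher and 1 lower of 23 (adjusted p 0.094), epithelial and stromal markers 4 higher of 16 (5 over the list alone; 0.103), and megakaryocyte and platelet genes 2 higher of 11 (1 over the list alone; 0.458). Genes of G2 and mitosis had 4 lower of 26 (0.72), with the cyclin CCNA2 at -0.65 (SE 0.15). Of 6 MHC class I presentation genes 1 was higher and 3 lower (0.44), of 13 DNA methylation enzymes 1 was higher and 1 lower (0.981), and of 8 erythroid genes 1 was higher and 1 lower (0.981). In the lists that were called here, median, mean and camera direction had the same sign. They differed in sign for 3 that were not: the medians of epithelial and stromal markers (-0.01), DNA methylation enzymes (-0.06) and erythroid genes (-0.06) were below 0 and their means above 0, and camera pointed down for erythroid genes and up for the other two. MHC class II presentation had 3 measured genes, too few for the test, of which RFXAP was lower at -0.57 (SE 0.14). The list of polyadenylated histone genes had no member among the named probe sets.

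**Figure D3:**
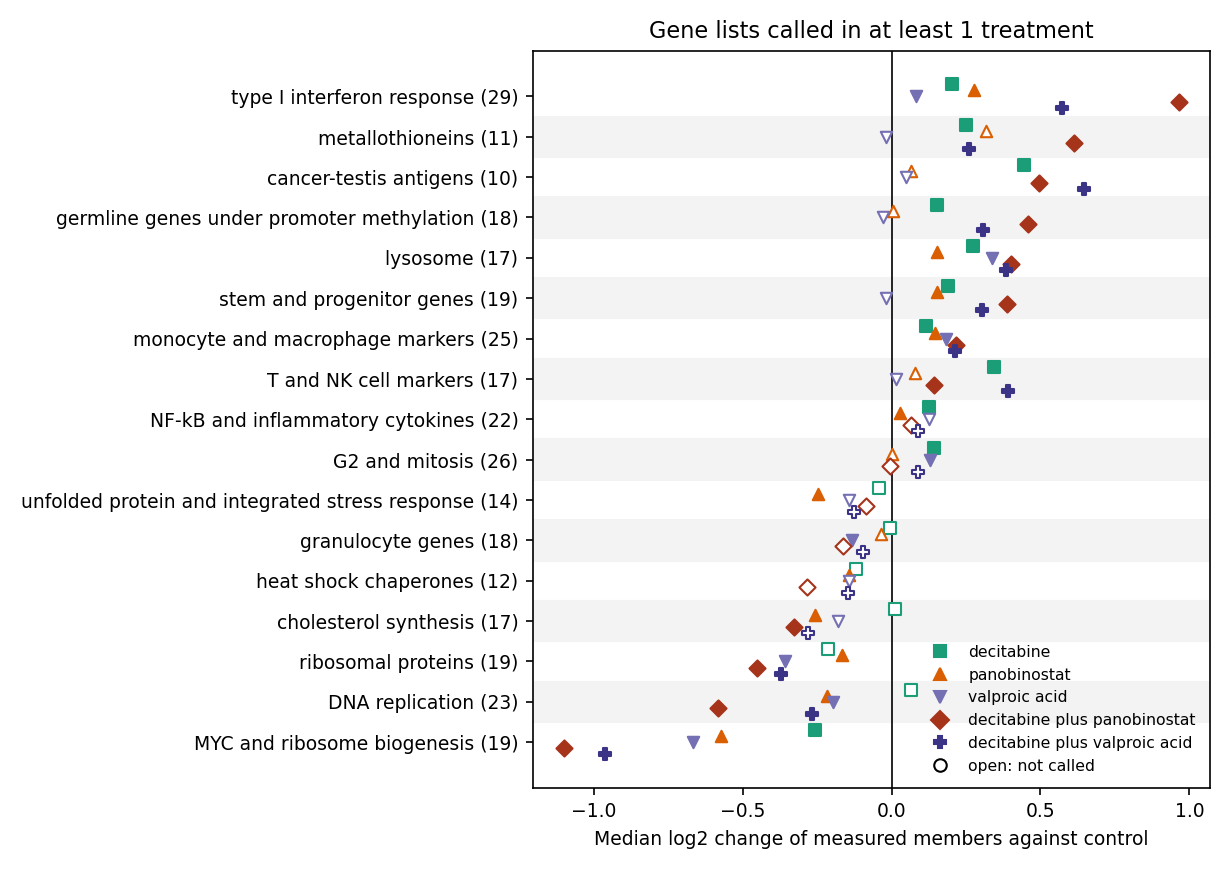
Each marker is the median log2 change against control of the measured members of a list (number measured in brackets), with color and shape for the treatment and filled where the camera test called the list. Interferon response genes had their highest median with decitabine plus panobinostat (0.97), and genes of MYC and ribosome biogenesis were called lower in all 5 treatments, though not with decitabine (0.218), panobinostat (0.138) or valproic acid (0.0748) under an estimated correlation.

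Decitabine plus valproic acid against control shows the whole effect of the second combination. CD34 rose by 5.04 (SE 0.28), TKTL1 by 4.82 (SE 0.34), MAEL by 4.48 (SE 0.25), PRF1 by 4.41 (SE 0.26) and the antioxidant enzyme PRDX1 by 3.72 (SE 0.16). JADE2 fell by 3.01 (SE 0.20), TFAP4, a transcription factor that MYC activates, by 1.78 (SE 0.33) and MTHFD1L by 1.65 (SE 0.20). Of 2524 genes called 1325 were higher and 1199 lower, with 503 and 211 at 2-fold or more. The count was 2547 without replicate 1 of this group, the array nearest to the decitabine arrays, and 1381 genes were called whichever array was left out.

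With this combination 11 lists were called, 8 higher and 3 lower. Of 19 genes of MYC and ribosome biogenesis 14 were lower (17 over the list alone), with a median of -0.96; MYC fell by 1.59 (SE 0.22) and RRS1 by 1.41 (SE 0.23). Higher were 13 of 29 interferon genes (15 over the list alone), with IFIT5 at 2.65 (SE 0.35), IFI44L at 1.53 (SE 0.26) and RIGI at 1.37 (SE 0.15); 7 of 18 germline genes, with TEX14, needed for bridges between germ cells, at 1.92 (SE 0.20); and 6 of 10 cancer-testis antigens (7 over the list alone), with PRAME at 2.64 (SE 0.23). So were 8 of 17 lysosome genes, with the protease CTSD at 0.96 (SE 0.12); 7 of 17 T and NK cell markers (8 over the list alone), with CD2 at 2.04 (SE 0.22); 7 of 19 stem and progenitor genes (9 over the list alone), with GATA2 at 2.75 (SE 0.24), while 1 of these was lower; and 9 of 25 monocyte and macrophage markers, with TYROBP at 2.68 (SE 0.17), while 2 were lower. The adjusted p of these 8 lists was 1.81e-13, 4.52e-06, 1.04e-05, 1.84e-05, 3e-05, 9.54e-05, 0.000601 and 0.000601. The values with an estimated correlation, the highest of the alternatives, ran from 0.0118 to 0.022, and the lowest alternatives ran from 1.65e-13 to 7.27e-06. DNA replication genes (6 of 23 lower, 8 over the list alone), metallothioneins (4 of 11 higher) and ribosomal proteins (8 of 19 lower) had an adjusted p of 0.000733, 0.00326 and 0.00369, which became 0.19, 0.09 and 0.178 with an estimated correlation (lowest alternatives 0.000677, 8.06e-05 and 0.00134).

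Adding panobinostat to decitabine, compared with decitabine alone, asks what the inhibitor adds. DHRS2 rose by 4.04 (SE 0.43), ENPP2, which makes lysophosphatidic acid, by 3.92 (SE 0.42), the tight junction protein TJP3 by 3.18 (SE 0.31) and CXCL11, an interferon-induced chemokine, by 2.88 (SE 0.31). PRTN3, proteinase 3 of neutrophil granules, fell by 3.19 (SE 0.28) from the level it had reached with decitabine, and JADE2 fell by 2.50 (SE 0.20). Of 2317 genes called 1140 were higher and 1177 lower, with 356 and 230 at 2-fold or more; 1206 were called whichever array was left out. Lower were 18 of 23 DNA replication genes (19 over the list alone; MCM7 at -1.11, SE 0.15), 15 of 19 of MYC and ribosome biogenesis (18; RRS1 at -1.33, SE 0.23), 6 of 18 granulocyte genes (1 higher and 7 lower; PRTN3, and AZU1 at -1.43, SE 0.19) and 4 of 17 of cholesterol synthesis (9). Of 29 interferon genes 18 were higher and 1 lower (19 and 1), with OASL at 1.56 (SE 0.15). The adjusted p was 3.43e-14, 2.62e-13, 0.00395, 0.0016 and 1.97e-10. Estimating the correlation, the highest of the alternatives, gave 0.0271, 0.0368, 0.0276, 0.0276 and 0.0121, and the lowest alternatives were 2.93e-14, 9.41e-14, 2.42e-06, 1.9e-05 and 1.02e-10. 7 more lists were called with the preset correlation and lost with an estimated one, at adjusted p between 0.0713 and 0.193.

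Decitabine plus panobinostat, compared with panobinostat alone, asks what decitabine adds. TKTL1 rose by 6.01 (SE 0.34), CXCL11 by 3.76 (SE 0.31) and CD34 by 3.74 (SE 0.28). TYRP1 fell by 2.32 (SE 0.16) and TSPAN8 by 1.80 (SE 0.14). Of 1421 genes called 806 were higher and 615 lower, with 318 and 94 at 2-fold or more; the count was 882 without panobinostat replicate 1, and 652 genes were called whichever array was left out. Higher were 17 of 29 interferon genes (20 higher and 1 lower over the list alone; IRF7 at 1.63, SE 0.26), 8 of 18 germline genes, 4 of 10 cancer-testis antigens (5), 6 of 17 T and NK cell markers, 6 of 19 stem and progenitor genes (8 higher and 1 lower), and 4 of 25 monocyte markers with 2 lower (9 and 2). Their adjusted p was 1.32e-15, 5.19e-08, 3.5e-06, 0.000293, 0.00154 and 0.0149. The estimated correlation, the highest of the alternatives, gave 0.00169, 0.0133, 0.0049, 0.0133, 0.0235 and 0.0433, and the lowest alternatives were 3.35e-16, 3.54e-09, 5.13e-07, 2.07e-06, 1.41e-05 and 6.7e-05. Lower were 9 of 19 genes of MYC and ribosome biogenesis (13 over the list alone) and 8 of 23 of DNA replication (12), with adjusted p of 6.17e-09 and 4.21e-07, and 0.0633 for each with an estimated correlation (lowest alternatives 2.91e-09 and 3.89e-07). Lysosome genes, metallothioneins and imprinted genes were also called higher and lost with an estimated correlation, at adjusted p of 0.0509, 0.111 and 0.0633.

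Adding valproic acid to decitabine changed fewer genes than adding panobinostat, at doses that are not matched: 913 were called, 531 higher and 382 lower, with 179 and 44 at 2-fold or more. CD22 rose by 2.58 (SE 0.27), TJP3 by 2.51 (SE 0.31), ADAM28 by 2.20 (SE 0.21) and CXCL11 by 2.19 (SE 0.31). JADE2 fell by 2.50 (SE 0.20), PRTN3 by 2.08 (SE 0.28) and the chromatin remodeler CHD3 by 1.32 (SE 0.17). The largest rise, of DHRS2 by 3.02 (SE 0.43), had an adjusted p of 0.0011 and of 0.0579 with only these 6 arrays in the fit (0.000358 to 0.0579 over the alternatives). Of 19 genes of MYC and ribosome biogenesis 10 were lower (14 over the list alone), of 23 of DNA replication 5 (11), and of 18 granulocyte genes 5. Their adjusted p was 1.42e-12, 2.26e-08 and 0.0122, and 0.102, 0.108 and 0.102 with an estimated correlation (lowest alternatives 9.45e-13, 2.24e-08 and 0.00068). Neuronal genes, 2 of 23 higher (4 over the list alone; adjusted p 0.0266), were lost without decitabine replicate 3 (0.0638). Lysosome genes, 1 of 17 higher (0.0334), were lost without decitabine replicate 2 (0.0815), decitabine replicate 3 (0.0638) or replicate 2 of the combination (0.0703). These 2 lists were, with an estimated correlation, at 0.148 and 0.201 (lowest alternatives 0.00677 and 0.0147). This count rested on few arrays: it was 520, 563 and 443 without decitabine replicates 1, 2 and 3, 376 and 360 without replicates 2 and 3 of the combination, and 177 with only these 6 arrays in the fit. Without replicate 1 of the combination it was 1227, and 253 genes were called whichever array was left out.

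Decitabine plus valproic acid, compared with valproic acid alone, asks the same of the second combination. TKTL1 rose by 4.96 (SE 0.34), MAEL by 4.76 (SE 0.25), CD34 by 4.08 (SE 0.28) and PRF1 by 3.42 (SE 0.26), while CAPN6 fell by 1.87 (SE 0.29) and TYRP1 by 1.76 (SE 0.16). Of 600 genes called 391 were higher and 209 lower, with 196 and 36 at 2-fold or more. The count was 381 without valproic acid replicate 2, 371 without valproic acid replicate 3 and 261 with only these 6 arrays in the fit, and 265 genes were called whichever array was left out. Higher were 6 of 18 germline genes (8 over the list alone), 5 of 10 cancer-testis antigens (7), 6 of 17 T and NK cell markers (8), and 6 of 19 stem and progenitor genes (9 higher and 2 lower). Their adjusted p was 9.03e-09, 3.65e-08, 3.47e-06 and 2.82e-05. Estimated correlations, the highest of the alternatives, gave 0.00765, 0.00207, 0.00333 and 0.00549, and the lowest alternatives were 7.33e-11, 2.58e-08, 2.38e-06 and 2.38e-06. Interferon genes, 9 of 29 higher (11 higher and 1 lower), had an adjusted p of 0.000158 and of 0.0635 with an estimated correlation (lowest alternative 0.000101). 4 more lists, among them MYC and ribosome biogenesis with 1 of 19 lower (8 over the list alone), were called and lost with an estimated correlation, at adjusted p between 0.0637 and 0.236. Of these, imprinted genes (0.0256) were also lost without replicate 1 of the combination (0.0916) or valproic acid replicate 2 (0.086), and monocyte markers (0.0426) without replicates 1 and 2 of the combination (0.0916 and 0.0593) or valproic acid replicate 2 (0.0853).

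The interaction of decitabine and panobinostat tests whether the combination departed from the sum of the single changes on the log2 scale. Of 93 genes called 50 had a positive and 43 a negative interaction. CXCL11 rose beyond the sum by 2.96 (SE 0.44): its level was 3.60 (SD 0.24) in control, 4.40 (SD 0.56) with decitabine, 3.52 (SD 0.22) with panobinostat and 7.28 (SD 0.60) with both. As its levels in control and with panobinostat, like those of DPPA3, lay under the median of all values (3.84), the sizes of these interactions are uncertain. The testis chaperone gene HSPA2 had an interaction of 2.22 (SE 0.21), the pluripotency gene DPPA3 of 2.35 (SE 0.34), and RGS16, a regulator of G protein signaling, of 2.20 (SE 0.36). PRTN3 rose by 3.04 (SE 0.28) with decitabine and was at 4.43 (SD 0.47) with both agents, close to its control level of 4.58 (SD 0.32), an interaction of -2.71 (SE 0.39). LGR5, which both agents raised alone, had -2.37 (SE 0.34), BMP2 -1.94 (SE 0.26) and CD86 -1.55 (SE 0.26). These 8 kept the call with any 1 of 12 arrays left out, as 40 of the 93 did. By direction, 42 of the 93 went higher and 9 lower beyond the sum, 23 and 2 fell short of it, and 17 were not called with the combination. The count was 50, 46, 61, 60 and 59 without control replicate 2, control replicate 3, decitabine replicate 2, decitabine replicate 3 and replicate 3 of the combination, and without control replicate 3 it had 22 positive and 24 negative. Of the 3447 genes called with the combination 2251 were called with neither agent alone, and 34 of these had a called interaction.

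Interferon genes had a positive interaction as a list, with a median of 0.56 and an adjusted p of 2.46e-06 in the camera test, and of 0.0538 with an estimated correlation (lowest alternative 1.49e-06). Of 29 members 3 were called (13 over the list alone), with OASL at 1.24 (SE 0.21). IFI44L (adjusted p 0.026) was lost without control replicates 2 and 3 (0.0587 and 0.0726), decitabine replicate 2 (0.0619), panobinostat replicates 1 and 3 (0.0627 and 0.0579) and replicates 1 and 3 of the combination (0.0695 and 0.0689). XAF1 (0.0399) was lost without any array but decitabine replicate 2 and panobinostat replicate 2 (0.0575 to 0.107). In a fit of only these groups they were at 0.0525 and 0.0535. DNA replication genes had a negative one, with a median of -0.39 and an adjusted p of 2.41e-10, and granulocyte genes a median of -0.18 with 0.0116; both were at 0.0538 with an estimated correlation (lowest alternatives 1.73e-10 and 0.00536). In DNA replication 1 of 23 members was called (9 over the list alone), and among granulocyte genes 1 of 18 (2), PRTN3. MYC and ribosome biogenesis (median -0.26, no member called, adjusted p 0.00753) had 0.484 with an estimated correlation (lowest alternative 0.00432) and 0.278 with fry. 3 more lists were lost without single arrays: genes of G2 and mitosis (0.0149) without replicate 1 of the combination (0.0861), imprinted genes (0.0144) without control replicate 1 (0.075), and germline genes (0.0414) without control replicate 3 (0.0835), decitabine replicates 2 and 3 (0.124 and 0.106), replicates 1 and 3 of the combination (0.355 and 0.0506) or panobinostat replicates 1 and 2 (0.087 and 0.0724). With an estimated correlation these 3 had an adjusted p of 0.15, 0.1 and 0.38 (lowest alternatives 0.0117, 0.0117 and 0.0262).

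The interaction of decitabine and valproic acid had 9 called genes, 2 positive and 7 negative, and 1149 at an unadjusted p under 0.05. HSPA2 rose beyond the sum by 1.82 (SE 0.21; adjusted p 0.0028), and LGR5 fell short of it, with -2.53 (SE 0.34; adjusted p 0.0081); these kept the call with each array left out, but LGR5 had an adjusted p of 0.0561 with only these 4 groups in the fit (0.00526 to 0.0561 over the alternatives). The count was 26, with 17 positive and 9 negative, without replicate 1 of the combination, and 3 without its replicate 2 and 5 without valproic acid replicate 1, and 3 genes were called whichever array was left out. Genes of G2 and mitosis were the only list called (median -0.15, no member called, adjusted p 0.015). They were lost without replicate 2 of the combination (0.0821), without valproic acid replicate 3 (0.091), with fry (0.0536) and with an estimated correlation (0.194; lowest alternative 0.00922).

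**Figure D4:**
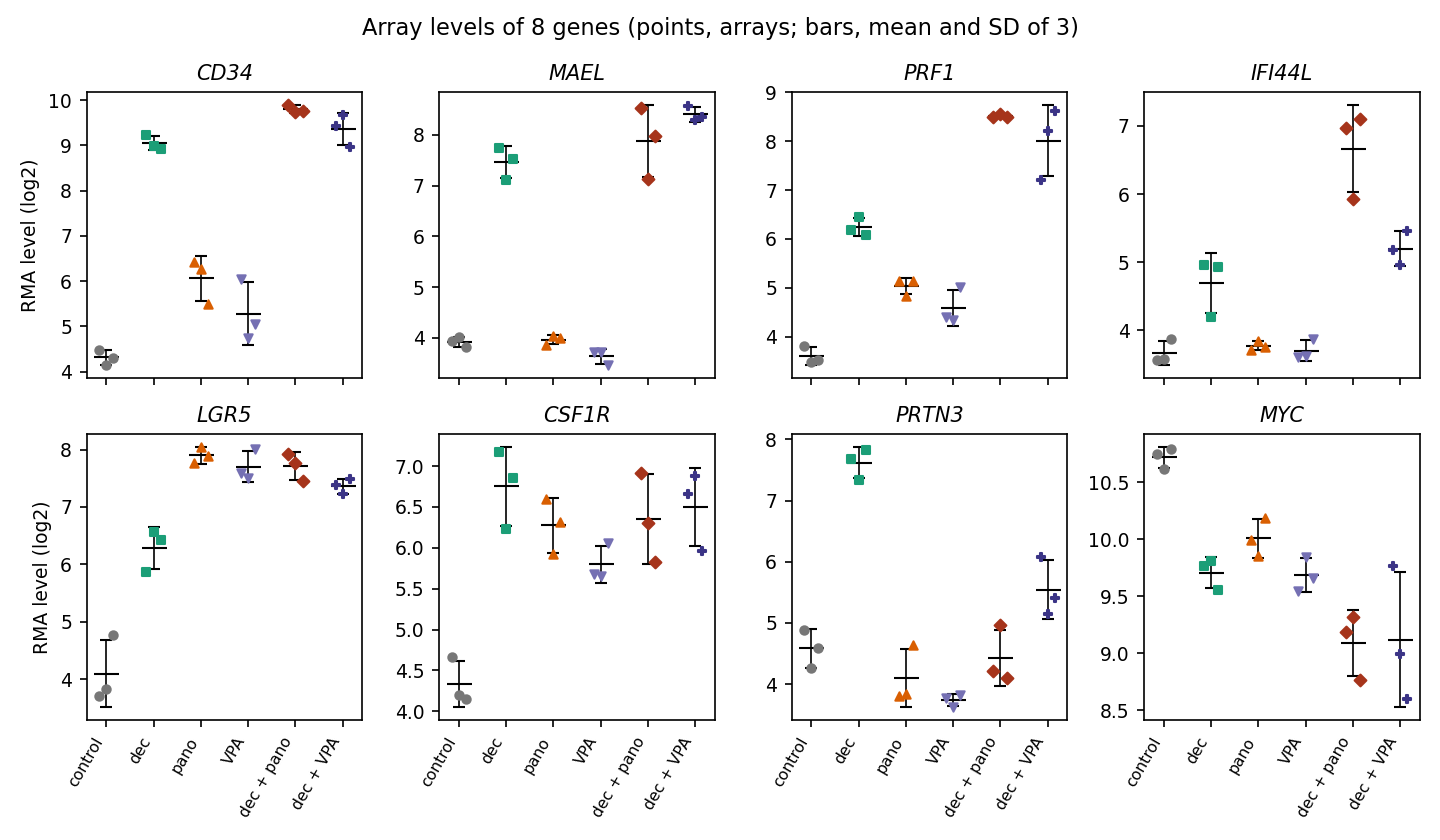
Points are the RMA levels (log2) of 8 genes on each of the 18 arrays by group, with the mean and SD of the 3 arrays of a group as bars. CD34 and MAEL were high in every group with decitabine, IFI44L was highest with decitabine plus panobinostat, and PRTN3 was highest with decitabine alone.

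Set against each other at doses that are not matched, the combinations differed in 97 genes, 55 higher and 42 lower with panobinostat. LAIR2, a soluble collagen receptor, was higher by 2.20 (SE 0.33) and the cytokine receptor CRLF2 by 1.75 (SE 0.19), with adjusted p of 0.0084 and 0.0012, and both kept the call with each array left out and in the 7 alternatives run for single genes, which leave out treat. With only these 6 arrays in the fit they were the only 2 genes called. Interferon genes were higher with panobinostat, 8 of 29 (12 over the list alone), with a median of 0.43: OASL was higher by 1.17 (SE 0.15) and IFIT3 by 1.05 (SE 0.15), at adjusted p of 0.0039 and 0.0069, and of 0.135 and 0.202 with only these 6 arrays (lowest alternatives 0.00361 and 0.00501). The list had an adjusted p of 5.11e-16 and of 0.00149 with an estimated correlation, the highest of the alternatives (lowest 9.35e-17). DNA replication genes were lower, with 1 of 23 called (13 over the list alone) and a median of -0.32, and genes of G2 and mitosis had a median of -0.18 with none called. Their adjusted p was 1.16e-09 and 0.00136, and 0.0531 for both with an estimated correlation (lowest alternatives 8.96e-10 and 0.000831). The count of 97 was 29 and 53 without replicates 1 and 3 of decitabine plus panobinostat, and 26 and 37 without replicates 1 and 2 of decitabine plus valproic acid; 17 genes were called whichever array was left out. MYC and ribosome biogenesis (adjusted p 0.00865) had 0.751 without replicate 1 of decitabine plus valproic acid and 0.401 with an estimated correlation (lowest alternative 0.00806). The last 4 lists called here were lost with an estimated correlation and without single arrays. Monocyte markers (0.00874) were lost without replicate 3 of decitabine plus valproic acid (0.0842), and NF-kB and inflammatory cytokines (0.00865) without that array (0.146) or replicate 2 of decitabine plus panobinostat (0.0556). Cholesterol synthesis (0.0113) was lost without replicate 1 of decitabine plus valproic acid (0.145), and metallothioneins (0.0155) without that array (0.0685), its replicate 2 (0.128) or replicate 2 of decitabine plus panobinostat (0.082). With an estimated correlation these 4 were at 0.0531, 0.142, 0.0771 and 0.176 (lowest alternatives 0.00542, 0.00278, 0.01 and 0.00583).

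DNMT1, DNMT3A, DNMT3B, HDAC1, HDAC2, HDAC3 and HDAC6, which encode targets of the drugs, were among the genes to be named in every comparison. Against control, the maintenance methyltransferase gene DNMT1 was at 0.26 (SE 0.11) with decitabine, and the de novo enzyme gene DNMT3A was at 0.96 (SE 0.35) with decitabine; neither was called. DNMT3B rose by 1.23 (SE 0.19) with the first combination and by 1.40 (SE 0.19) with the second. With decitabine alone it was higher by 0.82 (SE 0.19) at an adjusted p of 0.0207, which became 0.109 without control replicate 1, 0.0781 without control replicate 2, 0.097 without decitabine replicate 1 and 0.0568 with only these 6 arrays. HDAC1, HDAC3 and HDAC6 were not called in any of the 5 treatments against control. Other histone deacetylase genes were: HDAC4 fell by 1.09 (SE 0.21) with the first combination and by 1.03 (SE 0.21) with the second, HDAC5 and HDAC9 rose by 1.36 and 1.35 with the first, and HDAC11 rose by 0.89 (SE 0.16) with the second. HDAC2 was lower with decitabine plus panobinostat, at -0.69 (SE 0.20; adjusted p 0.0193), without full separation of the arrays, and was lost without control replicate 2 (0.0946), control replicate 3 (0.0541), and replicates 1 (0.101) and 3 (0.0735) of the combination, and at 0.0631 with only these 6 arrays. MYC was lower with decitabine at -1.01 (SE 0.22; adjusted p 0.014), and lost without control replicate 1 (0.0532), control replicate 3 (0.0527) or decitabine replicate 3 (0.0617); with panobinostat it was at -0.71 (SE 0.22), not called (0.0617). The granule enzyme MPO fell by 0.73 (SE 0.14) with panobinostat, 0.79 (SE 0.14) with valproic acid and 0.93 (SE 0.14) with decitabine plus panobinostat. With decitabine plus valproic acid it was at -0.55 (SE 0.14; adjusted p 0.0113), and lost without replicate 3 of the combination (0.0691) and with only these 6 arrays (0.0728). The monocyte receptor CD14 was not called in any treatment.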

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

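Of the tests in this part, 3 were chosen after the result was seen: whether valproic acid was weaker in both arrays numbered 1, whether replicate 1 of decitabine plus valproic acid responded less to valproic acid, and whether RNA from T or NK cells was present.

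The 93 genes with a called interaction of decitabine and panobinostat stood out because the change with both agents differed from the sum of the single changes. The interferon list had a median interaction of 0.56. Weakly expressed genes whose single changes are compressed near the array's background could give such an excess, so 10000 lists were drawn, each member replaced by 1 of the 100 genes nearest to it in control level and in both single changes. The interferon list lay at percentile 100 of these lists, whose median was -0.11, and 21 of 29 members were positive. At the preset correlation the call held with any 1 of 12 arrays left out (adjusted p at most 5.44e-05, without replicate 1 of the combination). With an estimated correlation the adjusted p was 0.0538 and no array was left out. Batches are not labelled either, so an interferon response beyond additivity remains a hypothesis.

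Replicate 1 of decitabine plus valproic acid lay nearer decitabine alone than the other arrays of its group, at 0.475 of the way to them. They lay at 0.621 and 0.756 on other axes, so the spacing is not shown. A swap with a decitabine array was excluded, since the highest decitabine array lay at 0.185 on this axis, far below 0.5. Cells given decitabine alone under a wrong label were excluded too: over 1112 genes that valproic acid changed, this array followed the valproic acid change with a slope of 0.411, above the limit of 0.124 set by the decitabine arrays. Valproic acid was not weaker in everything numbered 1, as valproic acid replicate 1 had a slope of 1.19 against 0.807 and 0.951. The combination array had a slope of 0.411 over raised genes (0.705 and 0.731 in the other two) and 0.413 over lowered genes (0.616 and 0.802), which restates its position and decides nothing about the cause, so a smaller response to valproic acid in this array remains open.

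PRF1, LAT, LCK and CD2 rose with decitabine plus panobinostat in a line of monocytic lineage. RNA from T or NK cells could give such rises, but then the abundant markers should rise together. Over the 16 members other than PRF1 (LAT, LCK and CD2 included) the median rise was 0.14 (95% bootstrap bounds 0.06 and 0.905). This was under the 1 set for such RNA. GNLY (-0.11), NKG7 (0.11) and CD8A (0.02) were not called with the combination, while IL7R (1.12), GATA3 (0.90), CD5 (0.76) and NCAM1 (0.74) were called higher. Low control levels can hide rises (GNLY 3.98, CD8A 4.59, CD8B 3.56, CD28 3.76), so the test cannot exclude such RNA. Expression by the line itself remains a hypothesis.

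Other lists singled out by a difference between groups in the decitabine by panobinostat interaction were germline genes (median 0.21), granulocyte genes (-0.18), MYC and ribosome biogenesis (-0.26), G2 and mitosis (-0.15), DNA replication (-0.39) and imprinted genes (0.083). In this order their adjusted p was 0.38, 0.0538, 0.484, 0.15, 0.0538 and 0.1 with an estimated correlation, so none kept the call. In the decitabine by valproic acid interaction it was G2 and mitosis (-0.15), with 0.194. Single arrays also ended the call of G2 and mitosis for panobinostat (0.0861 without replicate 1 of the combination) and for valproic acid (0.0821 without replicate 2 of the combination and 0.091 without valproic acid replicate 3), and of imprinted genes (0.075 without control replicate 1). Germline genes lost it without control replicate 3 (0.0835), decitabine replicates 2 and 3 (0.124 and 0.106), panobinostat replicates 1 and 2 (0.087 and 0.0724) and replicates 1 and 3 of the combination (0.355 and 0.0506).

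The genes with the largest positive interaction of decitabine and panobinostat were CXCL11 (2.96), DHRS2 (2.89), BCAS1 (2.76), TJP3 (2.37), DPPA3 (2.35), ZNF32 (2.23), TKTL1 (2.23), HSPA2 (2.22), RGS16 (2.20) and ZNF280A (2.19), singled out because the combination differed from the sum. In control, CXCL11, DHRS2, BCAS1, DPPA3, TKTL1 and ZNF280A lay under the median of all values (3.84) and HSPA2 close to it, so the sizes and ranks of these interactions are uncertain. CXCL11, DPPA3, HSPA2, RGS16 and ZNF280A kept the call with each array left out, which does not address compression near background. DHRS2 (adjusted p 0.042) lost it without any of the 12 arrays, at 0.0614 to 0.106, and at 0.0627 with the replicate block. TKTL1 (0.047) lost it without control replicates 1, 2 and 3 (0.0753, 0.114 and 0.103), decitabine replicates 2 and 3 (0.105 and 0.0936), panobinostat replicates 1, 2 and 3 (0.0963, 0.0807 and 0.0993), replicates 1 and 3 of the combination (0.11 and 0.109) and with the replicate block (0.0622). BCAS1 (0.018) lost it without control replicates 2 and 3 (0.0503 and 0.0523), decitabine replicate 1 (0.0521) and replicate 3 of the combination (0.058), and TJP3 (0.019) without control replicate 3 (0.0555), decitabine replicate 1 (0.0567), panobinostat replicate 1 (0.0529) and replicate 3 of the combination (0.058). ZNF32 (0.015) lost it without control replicate 3 (0.0511).

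The genes with the largest negative interaction were ANKRD22 (-2.88), PRTN3 (-2.71), LGR5 (-2.37), CSF1R (-2.34), GLIPR1 (-2.08), BMP2 (-1.94), CXCR4 (-1.77), HOMER2 (-1.71), TSPAN8 (-1.61) and CD86 (-1.55), singled out in the same way. PRTN3, LGR5, GLIPR1, BMP2, TSPAN8 and CD86 kept the call with each array left out. CSF1R (adjusted p 0.015) lost it without control replicates 2 and 3 (0.0525 and 0.0523). ANKRD22 (0.021) lost it without control replicates 1 and 2 (0.0619 and 0.0651), decitabine replicates 1 and 2 (0.0589 and 0.0584), panobinostat replicate 1 (0.062) and replicate 3 of the combination (0.0608). HOMER2 (0.027) lost it without control replicates 1 and 2 (0.0555 and 0.0802), decitabine replicates 2 and 3 (0.0712 and 0.0695), panobinostat replicate 2 (0.0694) and replicates 1 and 3 of the combination (0.0527 and 0.0724). CXCR4 (0.028) lost it without control replicates 1, 2 and 3 (0.0753, 0.0554 and 0.0555), decitabine replicates 1 and 2 (0.0745 and 0.0798), panobinostat replicates 1 and 2 (0.0765 and 0.0662) and replicates 2 and 3 of the combination (0.0539 and 0.0785).

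The decitabine by valproic acid interaction had 9 called genes, of which 8 are protein coding: HSPA2 (1.82), MTMR11 (1.22), LGR5 (-2.53), GLIPR1 (-2.19), VNN1 (-1.37), SP110 (-1.23), TPM4 (-0.93) and LPXN (-0.81). HSPA2 and LGR5 kept the call with each array left out. GLIPR1 (adjusted p 0.011) lost it without replicate 2 of the combination (0.0563), TPM4 (0.015) without that array (0.0604) and valproic acid replicate 3 (0.0544), and SP110 (0.03) without control replicate 1 (0.0636), decitabine replicates 1 and 3 (0.0772 and 0.0765), valproic acid replicates 1 and 2 (0.0728 and 0.0567) and replicate 2 of the combination (0.0713). VNN1 lost it without any array but control replicate 3 and replicate 1 of the combination (0.0561 to 0.087), LPXN without any but control replicate 1 and replicate 1 of the combination (0.0563 to 0.0854), and MTMR11 without any but replicate 1 of the combination (0.0647 to 0.112). A fit of only these 4 groups ended the calls of LGR5 (0.0561), GLIPR1 (0.0767), VNN1 (0.0561), SP110 (0.0905), LPXN (0.0925) and MTMR11 (0.0767). The replicate block ended those of SP110 (0.0544) and MTMR11 (0.0677), quantile normalization applied again those of LPXN (0.0598) and MTMR11 (0.0631), and the filter on dim values that of LPXN (0.0541).

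Splitting the arrays of a comparison in other ways tests whether chance alone gives as many calls. For the decitabine by panobinostat interaction 3 of 100 splits, the real one included, called as many as 93, and for decitabine by valproic acid 5 of 100 called as many as 9. The highest other splits called 1291 and 356 genes, more than the real ones. These splits mix the treatments, so they do not show what chance gives without an interaction, and chance was not excluded by them. For the other 11 comparisons only 10 splits exist, too few for a share under 0.05. In each, 1 of 10 splits, the real one, called as many. The real counts ran from 18 to 3447, and the highest other split called 2 genes between the combinations, 1 for decitabine plus panobinostat against control, for either combination against decitabine and for decitabine plus valproic acid against valproic acid, and 0 in the rest.

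Probe sets without a gene name hold signal that the gene results leave out. Of 32128 such probe sets, 460 were higher than control with decitabine, 725 with panobinostat, 605 with valproic acid, 1803 with decitabine plus panobinostat and 1357 with decitabine plus valproic acid. Lower were 321, 437, 489, 1817 and 1318.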

How the results depend on the processing

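Testing every probe set on its own tests more features, named and unnamed, and gave 1358 calls with decitabine, 2210 with panobinostat, 2107 with valproic acid, 7015 with decitabine plus panobinostat and 5099 with decitabine plus valproic acid, each against control. Against a single agent the panobinostat combination had 4279 calls relative to decitabine and 2899 relative to panobinostat, and the valproic acid combination 1647 relative to decitabine and 1295 relative to valproic acid. The interactions had 222 calls for panobinostat and 28 for valproic acid, the inhibitors differed in 54 probe sets and the combinations in 195.

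A test against a 1.2-fold change asks for a larger effect. In the same order of comparisons it left 184, 340, 263, 1745 and 991 genes against control, then 823, 472, 152 and 206 for the combinations against single agents, 38 and 4 for the interactions, 0 between the inhibitors and 1 between the combinations.

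A fit with only the groups compared has fewer arrays behind its spread. It left 938 genes for the panobinostat combination against panobinostat, 177 and 261 for the valproic acid combination against decitabine and against valproic acid, 3 for the decitabine by valproic acid interaction, 0 between the inhibitors and 2 between the combinations. That interaction of 9 genes had 16 calls with trend and robust settings and 30 with array weights; the cause was not tested. The other counts stayed within 1.5 times the first value in these alternatives.

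Leaving out 1 array at a time, which lowers the number of arrays, gave 361 to 468 calls for decitabine, 659 to 854 for panobinostat, 508 to 1001 for valproic acid, 2811 to 2973 for decitabine plus panobinostat and 1759 to 2547 for decitabine plus valproic acid, each against control. For the panobinostat combination the range was 1675 to 1861 against decitabine and 882 to 1126 against panobinostat. For the valproic acid combination it was 360 to 1227 against decitabine and 371 to 565 against valproic acid. The interactions ranged from 46 to 98 and from 3 to 26, the inhibitors from 4 to 15 and the combinations from 26 to 109. The correlation of the panobinostat and valproic acid changes was 0.738 to 0.810 with an array left out and 0.791 to 0.804 in the other alternatives.

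The replicate number as a block gave 586, 1104, 1107, 3463 and 2551 calls against control. Of 45 pairs of arrays with the same number in different groups, residuals correlated at -0.108 to 0.104 with a median of 0.0197 (other numbers -0.0034), and 8 of 18 arrays correlated best with their own number, so the numbers were not taken as pairs. No named gene called in the first fit or in an alternative run for single genes changed sign between the fits. Nor did any list called in the first fit. Sign changes of genes called in neither fit were not counted, and lists not called in the first fit were not followed. The balance of calls did turn in the interactions. For valproic acid it went from 2 positive and 7 negative to 17 and 9 without replicate 1 of the combination, and for panobinostat from 50 and 43 to 22 and 24 without control replicate 3. With 3 arrays per group, many calls rest on each array, and 2199 of 3447 with decitabine plus panobinostat but 253 of 590 with decitabine were kept whichever array was left out. In the simulated data 35.8% of changes of 1.5-fold were recovered for decitabine against control, 40.3% for decitabine plus panobinostat against control and 14.9% for the interaction of these agents, and low signals limit this further, since they are compressed near the background.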

Other observations

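Genes that share a symbol stem were grouped into 150 families after the results were seen. Each family below was called with decitabine plus panobinostat at the preset correlation, and none with an estimated one, where the adjusted p was 0.101 for TIMM, MRPL, NUP and HOXB, 0.175 for TOMM and 0.278 for PCDHB. Of 13 measured TIMM genes, which import proteins into mitochondria, 11 were lower (median -0.98, adjusted p 8.46e-07 in the camera test), as were 8 of 10 TOMM genes of the outer membrane (-0.70, 0.000128). Among genes of the large mitochondrial ribosome subunit, MRPL, 26 of 48 were lower and 1 higher (-0.64, 2.69e-09), and 15 of 22 nucleoporins, NUP, were lower (-0.48, 2.32e-05). HOXB genes, homeobox factors of blood progenitors, were higher in 6 of 10 (0.64, 0.00859), and PCDHB genes, clustered protocadherins, in 5 of 16 (0.26, 0.0205). With decitabine plus valproic acid 10 of 13 TIMM, 17 of 48 MRPL and 4 of 10 HOXB genes were called in the same directions. These too lost the call with an estimated correlation, at 0.192 for each of the 3.

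By kind of transcript, 26.6% of 11916 protein-coding genes were called with decitabine plus panobinostat. Of 1398 long noncoding RNA genes 110 were higher and 73 lower, or 13.1%, and of 1072 microRNA genes 14 were higher and 24 lower, or 3.54%.

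A hypothesis set before the data were examined held that zinc finger genes, many of which repress retroelements, fall more often than other genes with decitabine. It was not borne out: 3 of 491 ZNF genes were called lower, or 0.611% against 1.42% of other genes, with a one-sided Fisher exact p of 0.969.

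A further hypothesis was that decitabine raises genes from lower starting levels than panobinostat does, as promoter methylation would keep them silent. Among 251 genes called higher with decitabine but not panobinostat 27.5% were below the median of all values in control, against 11.97% of 451 called higher with panobinostat but not decitabine (one-sided Fisher exact p 3.08e-07). Their median control levels were 4.54 and 6.54 on the log2 scale, against 4.53 for all genes tested, of which 37.7% lay below the median. As low levels are compressed and callable genes were not the reference, the source of this difference is open. Methylation was not measured, and genes are not independent of each other.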
